A study of Mus musculus with 8 samples.

How the data were processed

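RNA from the hippocampus of 8 male mice aged 8 weeks was measured on Affymetrix arrays, 4 from Kv10.1 knockout and 4 from wildtype animals. Per the labels' protocols, the hippocampus was dissected after carbon dioxide euthanasia, total RNA was extracted with Trizol, and biotinylated sense-strand DNA was made from 100 ng of total RNA with a whole-transcript labelling kit. The deposited values are log2 expression levels, 1 per probe set and array, given to 2 decimals. Per the submitters' processing notes, the tools were R 2.9, limma and RMA, a method that subtracts background, equalises the distributions of the arrays by quantiles and summarises the probes of a set. The order and settings of those steps are not given in the sources used here, nor is the version of the probe set definition, whose identifiers are gene numbers. The deposited arrays do not have identical distributions, since interquartile ranges run from 2.09 to 2.42. Signal over background and detection calls were not analysed here, so low levels could not be told from background.

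Arrays were assigned to genotype by their titles, and replicate numbers follow the order of the records and pair nothing. Each title gives its own mouse number, so replicates are separate animals. The lower series of numbers, 3749 to 3753, holds wildtype 1, 2 and 3 and knockout 1. The higher series, 3759 to 3763, holds wildtype 4 and knockout 2, 3 and 4. Series and genotype are thus largely confounded, and a fit with the series as a block separates them only in part. All 20985 probe sets entered the fit. The platform annotation gave 1 gene name for 19921 of them, several for 0 and none for 1064, making 19919 distinct names, and 19808 named probe sets were found in the gene table of assembly GRCm38.p6. That table supplied synonyms, chromosomes and gene order. None of its coordinates are printed, because the build behind the deposited values is not named.

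The comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, two-sided) with genotype as the single factor and Benjamini-Hochberg adjustment over all probe sets, at a threshold of 0.05. Kcnh1 also had an exact two-sided permutation test over the 35 splits of 8 arrays into 4 and 4. A set of 39 gene lists covering cell types, neighbouring brain regions, channels, receptors and signalling was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Of 864 listed names, 776 were matched, and a gene with several probe sets was represented by the one with the highest mean. A list score is the mean over its genes of log2 values centred on each gene's mean over the 8 arrays. Genes whose start lies within 5 Mb of Kcnh1 were compared with all other placed genes by Fisher's exact test on counts at an unadjusted p under 0.05, and by the ratio of mean squared moderated t.

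The comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Kcnh1, then up to 12 genes each way past the threshold. As fewer than 12 passed, it added the 10 higher and 10 lower genes with the smallest p, provided that the groups did not overlap and the mean lay above the median probe set. It also took up to 4 members with the smallest p, and any past the threshold, from lists called or set out in the text, all EAG family members, and 6 genes around Kcnh1. Further members of lists, Lyplal1, Bpnt1, Iars2, Tgfb2, Hhat, Syt14, Rcor3, Hsd11b1, Ttr and the genes that lead the first principal component were named after their values were seen.

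Alternatives were eBayes with an intensity trend or the robust option, array weights, repeated quantile normalization, median centring, removal of the dimmest 25% or 50% of probe sets, other rules for genes with several probe sets, the series of mouse numbers as a block, other thresholds and windows, other set tests, and each mouse left out in turn. Added after seeing the data were the first principal component as a covariate, the removal of both arrays that stand apart on it, and the EAG list without Kcnh1.

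The fit was tested on simulated data for the comparison of knockout with wildtype over 20985 probe sets. With independent noise, it recovered 2% of 50 genes changed 1.2-fold, 66% at 1.5-fold, 92% at 2-fold and 98% at 3-fold, with 5 false calls. With changes added to the real residuals under a regrouping that mixes the genotypes, it recovered 24%, 72%, 100% and 100%, with 120 false calls among the unaltered genes. That regrouping set knockout 1 and 2 and wildtype 1 and 2 against the other arrays. Both arrays that stand apart on the first principal component thus fell on one side, unlike in the comparison by genotype. These figures may therefore not carry over to that comparison. The same regrouping gave 1 call on those residuals with no change added and 0 on the deposited values. The unaltered genes had the same values in both runs, so the extra calls came from the Benjamini-Hochberg cutoff, which loosens when altered genes pass. Why so many unaltered genes lay near that cutoff was not tested. Genotype means had been removed from the residuals, which the fit did not take into account, so its recovery there may be too high. Camera with the preset correlation called 5 of 5 lists shifted by 0.3 and 0 of 34 others in the simulation with independent noise. Those lists were random genes without correlation, so the 0 says little about false calls among real lists, whose genes can move together. The shift of 0.3 was also larger than the mean difference of any list called in the real data, the largest being -0.163. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.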

Results

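Expression was measured in the hippocampus of 8-week-old male mice lacking Kv10.1 and of wildtype males, 4 animals per genotype. Kv10.1, also called Eag1, is a voltage-gated potassium channel found mainly in brain and is encoded by Kcnh1. The study set out to characterise the behaviour and function of these knockout mice, and the comparison made here asks which hippocampal transcripts differ when the channel gene is disrupted. Each array carried RNA from 1 mouse, so the spread within a group is the spread between animals. Values are the deposited log2 expression levels of 20985 probe sets, of which 19921 have 1 gene name, and differences are given as knockout minus wildtype. With 8 arrays, the median standard error of a difference was 0.0922 on the log2 scale.

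The arrays had similar levels, with medians between 7.5 and 7.55, and did not group by genotype. The mean Pearson correlation across probe sets was 0.988 for the 12 pairs of arrays of the same genotype and 0.988 for the 16 pairs of different genotype. The first principal component held 44.2% of the variance and set the array of wildtype 1 (score 32.0) and, less so, that of knockout 1 (score 14.9) apart from the other 6, which lay between -15.9 and 0.81. Wildtype 1 also had the widest interquartile range, 2.42 log2 units, and knockout 1 the next, 2.30. The lower series of mouse numbers ran from -3.58 to 32.0 on the first component and the higher from -15.9 to 0.81. The 2 series thus lay apart with a small overlap.

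Kcnh1 itself was lower in every knockout mouse. Its level was 8.35 ± 0.062 (SD, n = 4) in knockouts against 9.34 ± 0.131 (SD, n = 4) in wildtype mice, a 1.99-fold difference. On the log2 scale it fell by 0.99 with a standard error of 0.081 and a 95% interval from -1.17 to -0.81 (limma adjusted p = 0.00319). The 4 knockout values ran from 8.29 to 8.43 and the 4 wildtype values from 9.22 to 9.52, and an exact two-sided permutation test gave p = 0.0286, the smallest that 35 splits of 8 mice allow. The part of Kcnh1 that was deleted, and where the probes of this set lie relative to it, are not given in the sources used here, so the remaining signal cannot be read as transcript or as background.

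Kcnh1 was the single gene of 20985 past an adjusted p of 0.05. At an unadjusted p under 0.05 limma returned 664 probe sets, 343 higher and 321 lower, where 1049.25 would be expected by chance. All 4 knockout values lay on one side of all 4 wildtype values for 453 probe sets, 2.16% against the 2.86% that chance gives. The next gene was Tatdn3, a deoxyribonuclease-domain protein gene, with an adjusted p of 0.116, and every other gene had an adjusted p of 0.997 or more. Tatdn3 joined Kcnh1 past the threshold under 3 of the alternative fits.

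The other members of the EAG family of potassium channels, which includes the ERG and ELK channels, did not pass the test in either direction. Kcnh5, the closest relative of Kcnh1, was at 8.43 ± 0.148 (SD, n = 4) in knockouts and 8.58 ± 0.478 (SD, n = 4) in wildtype mice, a difference of -0.15 that turned to 0.09 without wildtype 1. The differences were -0.18 for Kcnh3, 0.06 for Kcnh7, 0.04 for Kcnh8, -0.03 for Kcnh2, 0.01 for Kcnh4 and -0.01 for Kcnh6, and all but that of Kcnh3 changed sign under at least 1 alternative fit. The Kcnh3 difference rested on wildtype 1, which read 9.07 against 8.42 to 8.68 in the other wildtype mice, and was -0.05 without it. As a group without Kcnh1 these genes had a median difference of -0.01 (unadjusted p = 0.585 by camera). The 28 measured genes of other voltage-gated potassium channels had a median difference of -0.02 (camera adjusted p = 0.626), or -0.08 without knockout 1 and 0.0042 without wildtype 1, with none past the threshold over all genes or adjusted over the list alone. Among 27 calcium-activated, inward rectifier and tandem-pore potassium channel genes, 1 passed when adjusted over the list alone. That gene was Kcnk2, the mechanosensitive tandem-pore channel TREK-1, at -0.38 ± 0.087 (SE; limma adjusted p over the list = 0.0378), whose gene lies near Kcnh1. This adjustment takes no account of the other lists looked at. The sodium, calcium and HCN channel list (adjusted p = 0.637) and the accessory subunit list (adjusted p = 0.81) were not called.

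Beyond the target, the genes with the smallest p whose groups did not overlap gave values that did not pass the test over all genes. Dcx, which encodes the microtubule protein doublecortin of newborn neurons, was 8.70 ± 0.056 in knockouts and 8.40 ± 0.022 in wildtype mice (SD, n = 4 each), a difference of 0.31. It passed when adjusted over the 16 genes of the adult neurogenesis list alone (limma adjusted p = 0.0101), an adjustment that takes no account of the 39 lists looked at. That list as a whole was not called (camera adjusted p = 0.315). Among its other members, Sox2 differed by 0.21 (0.13 without knockout 1), Eomes by 0.13 and Calb2, the calretinin gene, by -0.42. Higher values in knockouts were also read for Zbed6 (0.58), 1110032A03Rik (0.54), Gm8129 (0.53), Pnp (0.40), Cwc15 (0.36), Ywhaq (0.36), Fut9 (0.30), Far2 (0.27) and Flvcr1 (0.26). Lower values were read for Tatdn3 (-0.61), Gm12350 (-0.58), Ints7 (-0.50), Kpna2 (-0.47), Plekha2 (-0.38), Kcnk2 (-0.38), Rreb1 (-0.35), Inpp5j (-0.35), Ddx49 (-0.32) and Wrap73 (-0.31). All of these but Tatdn3 had a limma adjusted p of 0.997, and their standard errors ran from 0.063 for Dcx to 0.147 for Zbed6.

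**Figure D1:**
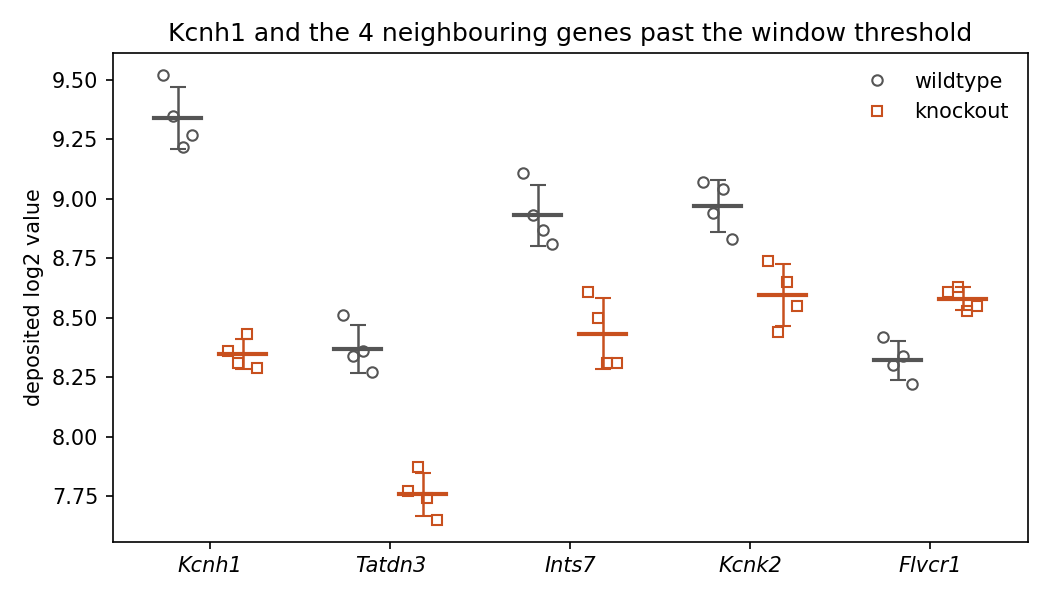
Deposited log2 value (vertical axis) of Kcnh1 and 4 genes near it on chromosome 1 in each of 4 wildtype mice (circles) and 4 knockout mice (squares), with bars at the mean and whiskers of 1 SD. Kcnh1, Tatdn3, Ints7 and Kcnk2 were lower and Flvcr1 was higher in all 4 knockouts than in any wildtype mouse.

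A cluster of genes close to Kcnh1 on chromosome 1 differed between the genotypes. Of the 46 genes within 5 Mb, 4 were at an unadjusted p under 0.05, and the same 4 passed when adjusted over the window alone. Tatdn3 (-0.61 ± 0.078, SE; limma adjusted p in the window = 0.00051), Ints7, a subunit of the Integrator complex (-0.50 ± 0.095; adjusted p = 0.0077), and Kcnk2 (-0.38 ± 0.087; adjusted p = 0.0215) were lower. Flvcr1, a heme and choline transporter gene, was higher (0.26 ± 0.070; adjusted p = 0.0409). The other 42 genes did not pass, including Slc30a1 (0.14), Camk1g (0.18, or 0.09 without wildtype 4), Hhat (0.09), Syt14 (0.08) and Rcor3 (0.01), adjacent to Kcnh1 in the order. Without single mice Hhat, Syt14 and Rcor3 ran from -0.04 to 0.18. All 4 lay on the side of Kcnh1 that holds 30 of the 46 genes, and none of the 16 genes on the other side, towards the chromosome end, was at an unadjusted p under 0.05.

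The mean squared moderated statistic of these 46 genes was 2.99 times that of 19761 other placed genes. This excess came from Tatdn3, Ints7, Kcnk2 and Flvcr1, with Tatdn3 the largest part, and the other genes of the window added none to it. The ratio therefore does not show a change across the whole window. The median log2 difference of the 46 genes was 0.0025. By count, 8.70% against 3.13% were at an unadjusted p under 0.05, which Fisher's exact test, two-sided, put at p = 0.056. Within 10 Mb the count was 8 of 74 (Fisher's exact p = 0.00222), where Lyplal1 (0.67), Bpnt1 (-0.51), Iars2 (-0.31) and Tgfb2 (0.25) joined the 4, and within 2 Mb it was 3 of 33 (exact p = 0.0843). For 20 Mb the count was 10 of 176 (exact p = 0.0757) and the ratio 1.70. The 10 Mb window was thus the single one under 0.05. The call by count changed with the fit, as set out among the alternatives. A fixed list of 40 neighbours passed fry's test for change in either direction (adjusted p = 0.0051), a test that does not compare it with other genes. Camera with the preset correlation, which looks for a shared direction, did not call that list (adjusted p = 0.751), and did so in 0 of 20 alternatives. Fry in one direction did not call it either (adjusted p = 0.678). Positions were taken from the GRCm38.p6 gene table for order and window only.

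**Figure D2:**
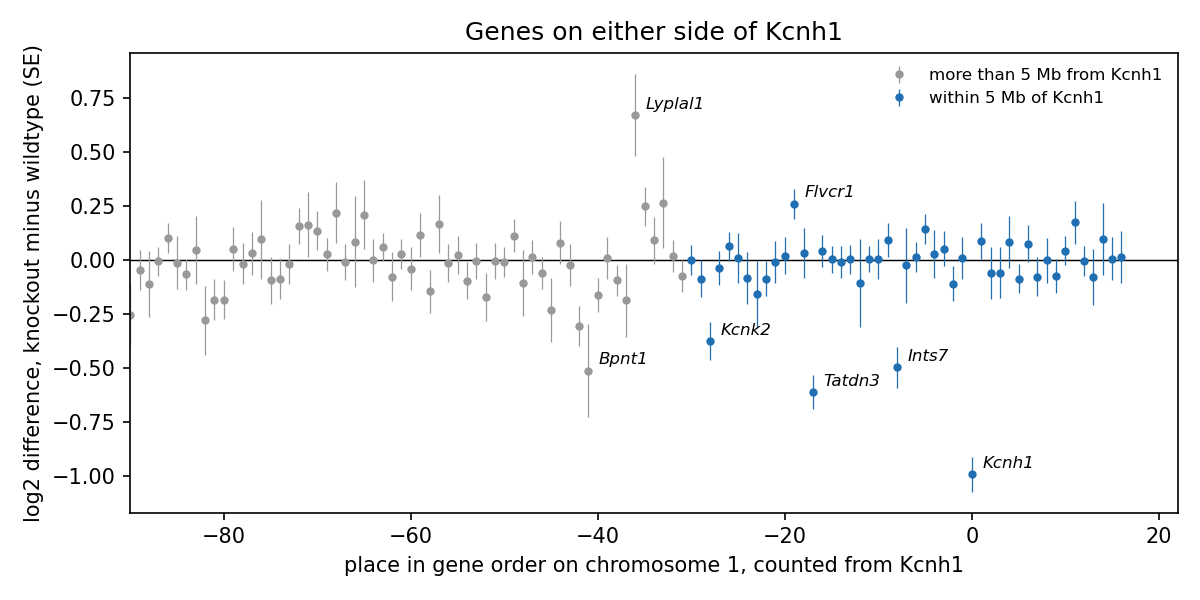
Log2 difference, knockout minus wildtype, with its standard error (vertical axis) for genes in their order on chromosome 1, counted from Kcnh1 at 0 (horizontal axis), with the 46 genes within 5 Mb and Kcnh1 in blue and farther genes in grey. Kcnh1 stands at -0.99 and Tatdn3, Ints7 and Kcnk2 at -0.61, -0.50 and -0.38, while most other genes in the window lie near 0.

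Glucocorticoid-response genes were lower as a group in the knockouts by camera with its preset correlation. The 18 genes of the list had a median difference of -0.17, with 14 lower and 4 higher (adjusted p = 0.000393 over 39 lists). The mean score of the list was below that of every wildtype mouse in all 4 knockouts. The call was lost with an estimated correlation (adjusted p = 0.352 with an estimated correlation, unadjusted p = 0.00903). No member passed over all genes or adjusted over the list alone. Zbtb16, a zinc finger repressor, read -0.32 ± 0.090 (SE), Fkbp5, the co-chaperone that restrains the glucocorticoid receptor, -0.31 ± 0.110, Nfkbia, the NF-kappaB inhibitor, -0.38 ± 0.146, and Tsc22d3, the glucocorticoid-induced leucine zipper, -0.25 ± 0.095. Sgk1 (-0.29) and Klf9 (-0.17) lay on the same side. The receptor genes Nr3c1 (0.11) and Nr3c2 (0.10) and the clock gene Per1 (0.07) did not. Without wildtype 1 the values lay closer to 0 for Nfkbia (-0.22), Sgk1 (-0.15), Klf9 (-0.09) and Nr3c2 (-0.0058). Nr3c1 was 0.07 without knockout 2 and 0.06 without wildtype 4, Nr3c2 0.16 without knockout 1 or wildtype 4, and Per1 0.02 without knockout 4, 0.0075 without wildtype 2 and 0.14 without wildtype 4.

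Markers of dentate granule cells, the principal neurons of the dentate gyrus, were also lower as a group. All 15 measured markers had a negative difference, with a median of -0.15 (camera adjusted p = 1.16e-05 with the preset correlation, adjusted p = 0.655 with an estimated correlation). The estimated correlation among them was 0.335 against the preset 0.01, so their shared sign does not count as 15 separate results. An exact permutation test of the list score gave an unadjusted p of 0.114, and fry in one direction 0.0763. Dsp, the desmoplakin gene, read -0.38 ± 0.107 (SE), Sema5b -0.20, Pdzd2 -0.19, Tdo2 -0.17, Calb1 -0.15 and Prox1, the granule cell transcription factor, -0.16. None passed over all genes or adjusted over the list alone. Prox1 is also 1 of the genes within 5 Mb of Kcnh1. Without wildtype 1 Pdzd2 was -0.12, without knockout 1 Tdo2 was -0.11, and Prox1 was -0.07 without knockout 1, -0.08 without knockout 2, -0.08 without wildtype 3 and -0.27 without knockout 4. The scores of knockout 1 (-0.20) and knockout 2 (-0.17) were the lowest, while knockout 3 (0.02) and knockout 4 (0.03) lay above wildtype 2 (-0.07). Markers of CA1 pyramidal neurons (median 0.01, mean 0.12, adjusted p = 0.209) and of CA2 and CA3 pyramidal neurons (median -0.03, adjusted p = 0.293) were not called. The CA1 score was 0.32 in knockout 2 against -0.12 to 0.03 in the other knockouts. The CA1 median was -0.0075 without knockout 2 and 0.10 without knockout 4.

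Genes of GABA receptors and the inhibitory synapse were higher as a group, by a median of 0.07 over 21 genes, 16 higher and 5 lower (camera adjusted p = 0.00769, adjusted p = 0.655 with an estimated correlation). Its members with the smallest p were the receptor subunit genes Gabrg3 (0.27 ± 0.085, SE), Gabrg1 (0.25 ± 0.110) and Gabra3 (0.29 ± 0.137), and the glycine receptor gene Glra2 (0.20 ± 0.093), and none passed over the list alone. Without knockout 3 Gabrg1 was 0.16 and Glra2 0.13. Without wildtype 4 the call ended (adjusted p = 0.0965), and the median was 0.12 without knockout 4 and 0.11 without wildtype 2. Interneuron markers, with a median of 0.10, were not called (adjusted p = 0.15), but were without knockout 4 (0.037) or wildtype 1 (0.025), with the mouse number block (0.0361) and with the first component as a covariate (0.0464), in a range up to 0.548. The median of the interneuron markers was 0.02 without knockout 1 (camera adjusted p = 0.548) and 0.06 without wildtype 4 (0.354). Within them Nos1 read -0.24, Calb2 -0.42, Dlx5 0.22 and Crh 0.16.

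Oligodendrocyte and myelin markers were higher by a median of 0.04 over 20 genes, 13 higher and 7 lower (camera adjusted p = 0.0385, adjusted p = 0.669 with an estimated correlation). The enzymes of myelin lipids Ugt8a (0.30 ± 0.093, SE), Fa2h (0.22 ± 0.083) and Aspa (0.17 ± 0.075) and the cytoskeletal gene Ermn (0.20 ± 0.090) had the smallest p, and no member passed over the list alone. That call ended without any 1 of knockout 2 (adjusted p = 0.148), knockout 3 (0.189), wildtype 2 (0.0943), wildtype 3 (0.333) or wildtype 4 (0.146), with the series of mouse numbers as a block (0.128) and with an intensity trend (0.0534). It strengthened without wildtype 1 (median 0.12, adjusted p = 1.26e-05) and without both arrays that stand apart (median 0.14, adjusted p = 5.8e-07). The median was 0.08 without knockout 1, 0.07 without knockout 4, and 0.02 without knockout 3 or without wildtype 2.

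Markers of the choroid plexus and ependyma, tissue that borders the hippocampus in the ventricle, were lower by a median of -0.13 over 20 genes, 16 lower and 4 higher (camera adjusted p = 0.00769, adjusted p = 0.669 with an estimated correlation). The score of wildtype 2 was 0.49 against -0.11 to 0.02 in the other wildtype mice, and its Ttr, the transthyretin gene of choroid plexus, read 12.43 where the other 7 arrays read 8.51 to 10.16. Without wildtype 2 the median was -0.04 and the call ended (adjusted p = 0.536), as it did without knockout 2 (adjusted p = 0.0644) and with the series of mouse numbers as a block (adjusted p = 0.138). It also ended with the dimmest 25% of probe sets left out (adjusted p = 0.12) and with the dimmest 50% left out, where 5 of the 20 markers remained, with a median of -0.35 (adjusted p = 0.671). Kl read -0.35, Steap1 -0.17, Calml4 -0.14 and Ccdc153 0.29. Without wildtype 2 Kl was -0.16 and Calml4 -0.08, and without knockout 1 Ccdc153 was 0.13.

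Genes of hypoxia and glycolysis had a median difference of -0.05 over 24 genes, 20 lower and 4 higher (camera adjusted p = 0.0288, adjusted p = 0.669 with an estimated correlation). Slc2a1, the glucose transporter GLUT1 of brain vessels and other cells, passed when adjusted over the list alone, at -0.47 ± 0.112 (SE; limma adjusted p = 0.0398). The same gene passed over the 23 endothelial and pericyte markers alone (limma adjusted p = 0.0381), a list that was not called (median -0.05, camera adjusted p = 0.0595). Over all genes the limma adjusted p of Slc2a1 was 0.997. Adjustment over a list alone takes no account of the 39 lists looked at, so some such passes can arise by chance. The endothelial list was called without knockout 2 (median -0.11, adjusted p = 0.00222), wildtype 2 (-0.09, 0.0117) or wildtype 4 (-0.12, 0.00297) and with median centring (0.0459), while its median was -0.0025 without wildtype 1 and its adjusted p ran up to 0.659 over 20 alternatives. Egln3 read -0.22, Epas1 -0.26 and Adm 0.19 (0.10 without knockout 3). The hypoxia call ended without wildtype 1 (median -0.02, adjusted p = 0.681), knockout 3 (0.0975) or knockout 4 (0.15) and with the series of mouse numbers as a block (0.738). It also ended with array weights (0.388), with the dimmest 25% (0.0856) or 50% (0.0664) of probe sets left out, with the first component as a covariate (0.164) and without both arrays that stand apart on it (0.359). Its median was -0.08 without knockout 2, -0.09 without wildtype 3 and -0.13 without wildtype 4.

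**Figure D3:**
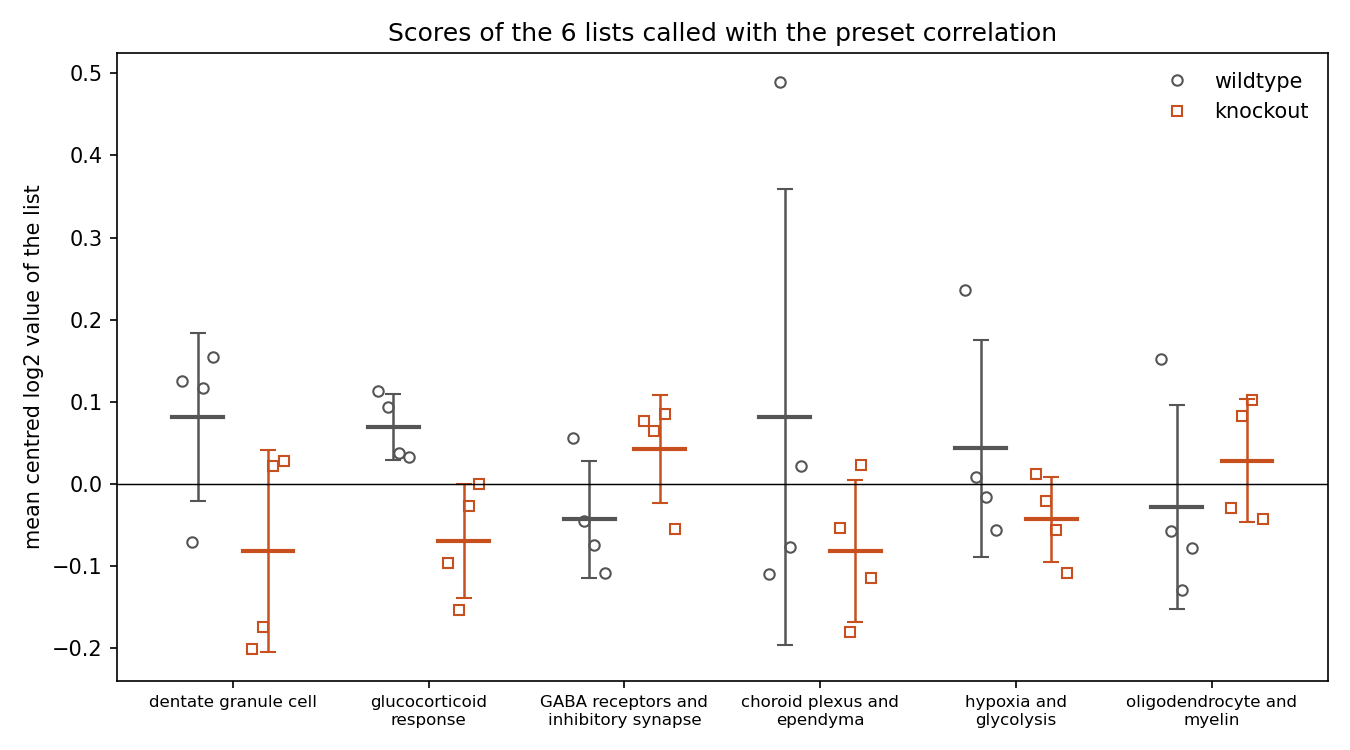
Mean centred log2 value (vertical axis) of each of the 6 gene lists called with the preset correlation (horizontal axis) in 4 wildtype mice (circles) and 4 knockout mice (squares), with bars at the mean and whiskers of 1 SD. All 4 knockouts lie below all 4 wildtype mice for the glucocorticoid list, and the genotypes overlap for the other 5, with wildtype 2 at 0.49 for the choroid plexus list.

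Of the 39 lists, those 6 were called with the preset correlation, 4 lower and 2 higher, and none with an estimated correlation. Activity-induced immediate early genes were not called (median 0.04, adjusted p = 0.172), with Nr4a1 at 0.41 ± 0.141 (SE), Nr4a2 at 0.31, Egr1 at 0.21 and Ier2 at -0.13, and none past the threshold over the list alone. Without wildtype 2 Nr4a1 was 0.27 and Egr1 0.11, and without knockout 4 Ier2 was -0.08. The immediate early gene median was 0.0021 without knockout 1 (camera adjusted p = 0.898). Microglia markers were not called (median 0.05, adjusted p = 0.135), although Ly86 read 0.50 and Ctss 0.33 against 0.13 for Cx3cr1 and -0.15 for C1qb. Without wildtype 1 Ly86 was 0.32, Ctss 0.22 and C1qb -0.03, and C1qb was -0.10 without knockout 2. The microglia median was 0.0042 without wildtype 2 and 0.02 without knockout 4. Dopamine signalling genes had a median of 0.03 (adjusted p = 0.81), with Pdyn at -0.26 (-0.14 without knockout 2) and Maob at 0.20 (0.13 without knockout 1, 0.31 without knockout 3, 0.10 without wildtype 4). The dopamine median was 0.065 without knockout 2 and -0.02 without knockout 3. Glutamate receptor and excitatory synapse genes (median 0.01, adjusted p = 0.675), calmodulin and calcium signalling genes (median -0.11, adjusted p = 0.192), synaptic vesicle release genes (median -0.05, adjusted p = 0.293) and clock genes (median -0.01, adjusted p = 0.466) were not called. Wildtype 1 carried the calmodulin difference, with a score of 0.26 against -0.07 to -0.01 in the other wildtype mice and -0.04 to -0.0049 in knockouts, and without it the median was -0.00083 (adjusted p = 0.681, the range over alternatives being 0.0601 to 0.819). Without wildtype 1 the vesicle release median was 0.01, the clock gene median 0.03 and the thalamus and habenula median -0.03. The striatum median was -0.01 without knockout 3. Of markers of tissue next to the hippocampus, the thalamus and habenula list (median -0.08, adjusted p = 0.135), the neocortex and subiculum list (median 0.02, adjusted p = 0.373), the striatum list (median 0.03, adjusted p = 0.81) and the meninges list (median -0.05, adjusted p = 0.096) were not called either. Single mice changed some of these calls: the meninges list was called without knockout 2 (adjusted p = 0.011), knockout 4 (median -0.10, 0.00534) or wildtype 4 (0.0401), in a range up to 0.525, and the thalamus list without knockout 3 (0.021) or wildtype 4 (0.0277), in a range up to 0.948. Without wildtype 1 the neocortex (0.0281), microglia (0.0281) and immediate early gene lists (0.025) were called as higher, in ranges up to 0.846, 0.382 and 0.898. A list of genes reported to differ between inbred mouse strains had a median of -0.02 with a camera direction upward (adjusted p = 0.751), and Ide, at 0.17, was the single member under an unadjusted p of 0.05.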

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

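The tests of wildtype 1 alone, of flanking DNA, of probe variants and of the granule list over splits were chosen after the results they bear on were seen. The patterns that the other tests weigh were also picked from the main results, so only the bounds of those tests were set in advance. Among 194 groups of 4 values, 11 had a mouse far from the other 3 by the ratio of its gap to the whole range, where chance gives about 9.7. In wildtype 1, 1110032A03Rik read 9.31 against 9.81 to 9.91 in the other wildtype mice (ratio 0.833) and Gm12350 8.88 against 8.36 to 8.40 (ratio 0.923). The same mouse stood apart for the scores of thalamus and habenula markers (0.36 against -0.10 to -0.03, ratio 0.852), synaptic vesicle release (0.20 against -0.05 to -0.01, ratio 0.85), sodium, calcium and HCN channels (0.16 against -0.05 to -0.03, ratio 0.893) and potassium channel accessory subunits (0.13 against -0.06 to -0.03, ratio 0.866). Wildtype 2 stood apart for Kl (9.37 against 8.57 to 8.69, ratio 0.85), for dentate granule markers (-0.07 against 0.12 to 0.15, ratio 0.831) and for cell cycle genes (-0.02 against 0.02 in the others, ratio 0.87). Among knockouts, Gabrg1 read 7.84 in knockout 3 against 7.43 to 7.48 (ratio 0.878), and knockout 4 had the low score for GABA and inhibitory synapse genes (-0.06 against 0.06 to 0.09, ratio 0.854).

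As many genes past the threshold as in the real grouping were found in 3 of the 35 splits of the 8 arrays, with 1 gene for the genotypes and 4 in the highest other split, so the count alone does not exclude chance. For the lists, 19 of the 35 splits called 6 or more with the preset correlation, up to 18 in the highest other split, and chance is not excluded there either. That highest split put wildtype 1 with knockouts 1, 2 and 3. Chance is not excluded for single lists either: a camera p as small came from 3 of the 35 splits for the granule list (2.96e-07 for the genotypes, 5.29e-13 in the best other split), 3 for the GABA list (0.000642 and 3.46e-05), 9 for choroid plexus (0.000788 and 4.67e-08), 10 for hypoxia (0.0037 and 0.000107) and 8 for oligodendrocytes (0.00592 and 2.18e-10).

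The lower level of the glucocorticoid-response list in knockouts was weighed against chance, cell makeup and single arrays. Of the 35 splits, 2 gave a camera p as small (2.02e-05 for the genotypes and 9.52e-06 in the best other split), so chance cannot be excluded. Without wildtype 1 the difference in list scores was -0.12 against -0.14 with it, which argues against that array as the cause. With the granule marker score as a covariate the difference was -0.10 ± 0.051 (SE), about 2 standard errors below 0, which the bounds set in advance leave undecided, so fewer granule cells in the knockout pieces and an effect of genotype cannot be told apart, although the lists share 0 genes. Hsd11b1, the corticosterone-regenerating enzyme gene that lies within the 5 Mb window, read 7.74 in both genotypes.

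The differences around Kcnh1 were weighed against a chance division of the mice, DNA carried along with the targeted allele, and probe artifacts. Only 1 of the 35 splits, the genotypes themselves, gave a ratio of mean squared moderated t as large (2.99, against 1.35 in the highest other split). That is the smallest share that 35 splits allow (0.0286), so the splits argue against chance but cannot exclude it. The ratio and the runs below rest mainly on Tatdn3, Ints7, Kcnk2 and Flvcr1. Over the whole genome 1 of 419 runs of 46 neighbouring genes was as high (3.42), and it lies beside Kcnh1 and shares 22 genes with the window. Farther than 20 Mb from Kcnh1, 0 of 415 runs of 46 neighbouring genes reached the mean squared value of 3.15 (highest 2.05), as flanking DNA of another strain carried with the targeted allele would give. Sequence variants under the probes that only weaken binding of the knockout allele would lower every affected gene, yet 1 of the 4 genes past the window threshold, Flvcr1, was higher; as the strains of the alleles are not given in the sources used here, these explanations cannot be told apart. A regulatory effect of the changed Kcnh1 locus on its neighbours was not tested and may give a local excess too.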

How the results depend on the processing

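The first component as a covariate, the removal of both arrays that stand apart on it and the EAG list without Kcnh1 were chosen after seeing the data. Kcnh1 kept its direction and its side of the threshold in 20 of 20 alternative fits, from -1.03 to -0.93 with limma adjusted p from 0.000225 to 0.0363. The count of genes past the threshold was 2, Kcnh1 and Tatdn3, with array weights, repeated quantile normalization and the first component as a covariate (limma adjusted p of Tatdn3 0.0437, 0.0451 and 0.0232), while its adjusted p ran up to 0.741 elsewhere. It was 68 (35 higher, 33 lower) at an unadjusted p under 0.01 with at least 1.2-fold, 664 at an unadjusted p under 0.05, and 1 without any single mouse. Lists called numbered 4 to 9 across fits, but 0 with an estimated correlation and 0 with fry in one direction. The granule and glucocorticoid lists were called in 20 of 20 fits with the preset correlation, the GABA list in 19, choroid plexus in 15, oligodendrocyte in 13 and hypoxia in 11. With the mouse number series as a block the hypoxia median was 0.02 (adjusted p = 0.738), and the choroid plexus (0.138) and oligodendrocyte (0.128) calls ended too. Of the 33 lists not called, 12 were called under at least 1 of these fits, among them CA1 markers (array weights 0.0108, without knockout 4 0.0386), neocortex markers (array weights 0.0039, without both apart arrays 0.00913), the list of tandem-pore and related channels (without wildtype 2 0.0266) and the EAG list with Kcnh1 (without wildtype 2 0.0228, without wildtype 3 0.0445, dimmest 50% left out 0.0485), with adjusted p up to 0.769, 0.846, 0.88 and 0.875 elsewhere.

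Around Kcnh1 the count moved past a Fisher's exact p of 0.05 with an intensity trend (4, p = 0.0488), median centring (5, p = 0.0144), the dimmest 25% or 50% of probe sets left out (4, p = 0.0378; 4, p = 0.0127), both apart arrays left out (5, p = 0.0208) and within 10 Mb (8, p = 0.00222). It was 4 to 5 without single mice, with exact p from 0.0176 to 0.0995, below 0.05 without knockout 2, 3 or 4 or wildtype 3. With the first component as a covariate it was 4 (exact p = 0.532), and within 20 Mb it was 10 of 176 (exact p = 0.0757, ratio 1.70). Of 23 alternatives, 13 left the exact p at 0.05 or above. The ratio of mean squared t within 5 Mb ran from 2.22 to 4.04 in 20 fits. The cause was not tested.

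Of 53 other named genes, 1028 of 1049 values kept their direction, and the 21 that reversed were in 6 EAG family genes, with differences of -0.15 for Kcnh5 and -0.03 to 0.06 for the others. The 53 leave out genes named only through other lists that were not called, or after their values were seen. With each mouse left out in turn, 10 of 115 named genes changed sign. They were the 6 EAG genes and Nr3c2, Rcor3, Eif2s3y and Kdm5d. Among the 53, genes outside the EAG family were mostly chosen for groups that did not overlap or for a small p. Their steady direction was therefore largely set by that choice, while the EAG genes were named regardless of p. Without both apart arrays the EAG list had a median of 0.033, Kcnh5 read 0.13 and Kcnh6 0.02. With array weights Kcnh2 read 0.0049 and Kcnh6 0.007, with median centring Kcnh6 read 0.0075, and with the mouse number block Kcnh2 read 0.0067, Kcnh8 -0.08 and Kcnh4 -0.0017. Without single mice Kcnh5 ran from -0.27 to 0.085, Kcnh7 from -0.0075 to 0.21, Kcnh2 from -0.075 to 0.032, Kcnh8 from -0.015 to 0.15, Kcnh4 from -0.028 to 0.046 and Kcnh6 from -0.04 to 0.0067. The cause was not tested.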

Other observations

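The remaining lists were not called by camera with the preset correlation. Astrocyte markers had a median difference of -0.05 (adjusted p = 0.64), oligodendrocyte precursor markers 0.01 (adjusted p = 0.81), interferon and innate immune genes -0.03 (adjusted p = 0.293), neurotrophin and growth factor genes -0.02 (adjusted p = 0.466) and cell cycle genes -0.02 (adjusted p = 0.524). Heat shock and unfolded protein genes (-0.04, adjusted p = 0.547), respiratory chain genes (-0.02, adjusted p = 0.902), serotonin and noradrenaline genes (adjusted p = 0.642) and blood cell markers (adjusted p = 0.91) were not called either. The heat shock list was called without wildtype 4 (median -0.09, adjusted p = 0.0277) in a range up to 0.944, and the sex-linked list without knockout 1 (adjusted p = 0.0297) in a range up to 0.792. Sex-linked genes (adjusted p = 0.135) read as in males in both genotypes, with Xist at 6.10 and 6.02 and Uty at 8.82 and 8.67 in knockout and wildtype mice.

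Several of the genes that varied most between mice were lowest in knockout 1 and wildtype 1. Gm13331, a gene inside Spopl, read 5.50 in knockout 1 and 5.77 in wildtype 1 against 8.38 to 10.12 in the other 6 mice, a range of 24.6-fold. Muc15, a mucin gene inside Ano3, ran from 5.96 in wildtype 1 to 9.38 in wildtype 4, and the receptor genes Lpar6, inside Rb1, and P2ry14, inside Med12l, ran from 7.73 to 10.31 and from 6.92 to 9.25. Kcnj13, an inward rectifier of choroid plexus that lies inside Gigyf2, ran from 7.32 in wildtype 1 to 9.91 in wildtype 2. At the other end of the first component, Rmrp read 12.24 in wildtype 1 against 9.80 to 10.50 in the other 7 mice, and Tac2 8.66 against 6.64 to 7.02. Tac2 is a member of the thalamus and habenula list, whose score was also highest in wildtype 1 (0.36). That score was -0.12 in knockout 1, and a part from neighbouring tissue in wildtype 1 was not tested.

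The first component was weighed as a trace of unspliced or genomic template, and no biological explanation was tested; the comparison of receptors with other genes of like level was chosen after its result was seen. Of the 50 genes lowest in the apart arrays, 27 lie wholly inside another gene, 54% against 2.38% of all placed genes. The 471 such genes had a median loading of -0.37 SD against -0.11 for genes of like level (lowest of 1000 random sets -0.25), so unspliced or genomic template in 6 of the arrays is a candidate explanation. Genomic DNA alone would also reach the 1261 olfactory and vomeronasal receptor genes outside other genes, whose median loading was -0.45, closer to 0 than level-matched genes inside others (-0.63, from -0.67 to -0.47 in 1000 random sets), which meets the bound set in advance against genomic DNA. They also lay beyond level-matched other genes (-0.38 to -0.29), as a part from genomic DNA would give, and 99.4% of them were below the median level, near the floor. That bound left out a mixture of both templates, so it is not taken as decisive, and the form of the template cannot be told apart here.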
